A study of Oryctolagus cuniculus with 8 samples.

How the data were processed

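RNA sequencing was used to measure gene expression in 8 samples of rabbit lung (Oryctolagus cuniculus). Total RNA was extracted with a Qiagen RNeasy kit, per the labels' protocols. The deposited values were a single table of raw counts, whole numbers of reads per gene for 23669 Ensembl rabbit gene IDs and 8 libraries, and the deposited counts carried no normalization. Trimmomatic 0.36, STAR 2.5.2b, DESeq2 and the genome build OryCun2.0 are named in the submitters' processing notes. The program that counted the reads, the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads from overlapping, antisense or near-identical genes can therefore be split or lost in ways that the counts do not show. Every line of the table had a gene ID, and 3835 IDs had no count in any library.

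The count table gives gene IDs without gene names or coordinates. The gene name table at hand describes another rabbit assembly (mOryCun1.1) and lists 0 Ensembl IDs, so 0 of the 23669 IDs could be paired with a symbol. The 37 lists of genes (pathways, lung cell types, other cell types and quality markers) that had been fixed before the data were examined could therefore not be matched, and no gene list was tested. The rule for named genes, also fixed beforehand, took called genes with a symbol, a mean of 5 CPM (counts scaled to equal library totals) or more in the higher group and no overlap between the libraries of both groups, ordered by fold change. Its other parts named genes by symbol. Without symbols, the IDs named here are the 2 with the largest rise and the 2 with the largest fall in the treprostinil comparison that met the remaining conditions, which 41 higher and 141 lower IDs did. Other IDs are described by their values only, and those were chosen for the text after their values were seen, from the 8 largest changes per direction under the same conditions.

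Groups were taken from the sample titles: 3 lungs with congenital diaphragmatic hernia (CDH) without treprostinil, labelled placebo in the treatment field and unexposed in the title, 3 CDH lungs exposed to treprostinil, and 2 control lungs without treprostinil. Each title begins with a code number, and no code holds libraries of more than 1 group: 61 (2 libraries) and 56 (1 library) for placebo CDH, 81 for exposed CDH, and 83 for controls. The labels do not say what the code stands for. A model with a term for each code leaves no group difference to estimate apart from the codes, so group differences and code differences cannot be told apart. Placebo CDH replicates 1 and 2 carry code 61 and replicate 3 carries code 56, with replicate numbers given in accession order. In the other groups the replicate number is the last number of the title's code. No label says whether libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

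Counts were analysed with edgeR 4.0.16 in R 4.3.3. IDs were filtered with filterByExpr on the groups, which left 14507 IDs and removed at most 0.0574% of a library's counts. Library sizes were scaled by TMM, whose factors ran from 0.973 to 1.03. One quasi-likelihood model (glmQLFit, glmQLFTest) held all 8 libraries and 3 groups, with 5 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the IDs tested, within each of 3 comparisons. Standard errors of log2 fold changes were derived from the F statistic (1 numerator degree of freedom). CPM values of single IDs used TMM-scaled library sizes. Total counts per library ran from 9367924 to 22060353. No pair of libraries held identical counts. The chi-square of counts per degree of freedom, over IDs with 20 or more counts in a pair, was 12.4 to 56.0 within groups. Every library was therefore counted as 1 replicate. This spread does not show that libraries with the same title code are independent. If they are not, the p-values are too small.

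The fit was tested on simulated data: negative binomial counts with the real means, library sizes and dispersions, in which 200 IDs were changed, averaged over 3 simulated tables for each comparison. For the treprostinil comparison, with a mean of 14357 IDs tested, 71.3% of the IDs changed by a fold of 2 and 88.3% of those changed by a fold of 4 were called, with 5.82% false calls. For placebo CDH against control (14364 IDs tested) the values were 59.0%, 88.7% and 4.32%, and for exposed CDH against control (14370 IDs tested) they were 61.3%, 87.3% and 5.89%.

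The alternatives fixed before the data were examined were RLE scaling, no filter beyond a total count above 0, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma 3.58.1 with voom, only the libraries of the groups compared, the last number of the title's code as a block, and leaving out each library in turn. Alternatives added after seeing the data were the fit without a run of 37 consecutively numbered IDs and 2 IDs that split the opposite way, and effects computed from different placebo CDH libraries, a test set down after the data were seen but before its own result was. Because the treprostinil and the CDH comparison share the placebo CDH libraries, unchanged groups were simulated 20 times to give the relation that arises without any effect. Overlaps of calls were set beside those of equally long lists, taken by smallest p in each direction from these simulated tables, a comparison added after seeing the data. Figures were drawn with matplotlib 3.10.9.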

Results

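Lung transcriptomes were compared in a rabbit model of congenital diaphragmatic hernia (CDH), a defect of the diaphragm in which the developing lung remains small and its vessels remodel. The hernia was made by surgery. Treprostinil, a stable prostacyclin analogue that dilates pulmonary vessels, was given on gestational day 24, with term at day 31. The duration of dosing and the day of lung collection are not given in the sources used here. The 8 libraries comprised 3 CDH lungs without treprostinil (placebo CDH), 3 CDH lungs with treprostinil (exposed CDH) and 2 control lungs. Total counts were 15713833, 9367924 and 14976796 for placebo CDH replicates 1 to 3, and 21937566, 22060353 and 15280569 for exposed CDH replicates 1 to 3. Control replicates 1 and 2 had 18032706 and 20510373 counts. Between 16759 and 17879 gene IDs had at least 1 count in a library. The most abundant ID took 2.07% to 3.38% of a library's counts, so no single gene dominated. The count table lists Ensembl IDs without gene names, and none could be paired with a symbol, so genes are described here by their levels and by how they moved across the groups.

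The 3 groups formed separate clusters. The first principal component of log2 CPM held 31.2% of the variance and placed placebo CDH libraries at -38.2 to -23.1, exposed CDH libraries at 5.04 to 19.2 and controls at 27.6 and 30.8. The second component held 23.6% and set exposed CDH (21.98 to 30.78) apart from controls (-33.2 and -26.6), with placebo CDH between them (-7.43 to -6.01). On the third component, with 11.6% of the variance, the placebo CDH library of title code 56 lay at 35.6 and the 2 of code 61 at -15.4 and -14.1. Pearson correlations of log2 CPM were 0.978 to 0.982 within placebo CDH, 0.981 to 0.985 within exposed CDH and 0.986 between the controls. Across groups they were 0.965 to 0.976 between placebo and exposed CDH, 0.963 to 0.969 between placebo CDH and control, and 0.970 to 0.974 between exposed CDH and control. These correlations are across genes, which are not independent replicates.

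**Figure D1:**
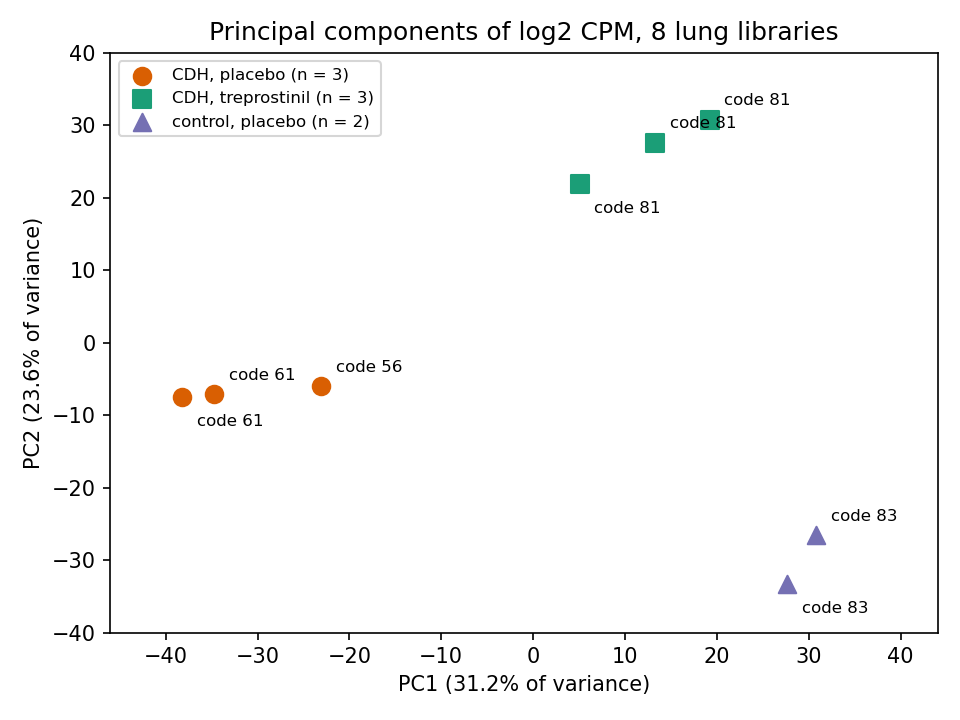
First and second principal components of log2 CPM over 14507 gene IDs, 1 point per library, colored by group and annotated with the code number that begins each sample title. Placebo CDH libraries lie at the left (-38.2 to -23.1 on the first component), and exposed CDH and control libraries lie to the right and separate on the second component.

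The treprostinil comparison asked which genes differed between exposed and placebo CDH lungs. Of 14507 IDs tested, 50 were higher and 156 were lower in exposed lungs (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), which is 1.42% of the IDs. Called genes were mostly lower in exposed lungs (75.7%) and mostly changed by less than a doubling: the median fold was 1.71 (quartiles 1.41 and 3.48) for the higher genes and 1.55 (quartiles 1.36 and 2.43) for the lower ones. A log2 change of 1 or more was reached by 21 higher and 48 lower IDs. The called genes were more abundant than the typical gene, with a median of 58.7 CPM against 23.8 CPM over all tested IDs, and the lower ones (67.1 CPM) were more abundant than the higher ones (33.5 CPM). In all 206 the libraries of both groups did not overlap, as was the case for 20.02% of all tested IDs, against 10% by chance for 3 libraries against 3.

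The largest rises among IDs that met the naming conditions were on/off changes in 2 abundant IDs. ENSOCUG00000026762 stood at 583 ± 58.8 CPM (SD, n = 3) in exposed and 2.06 ± 0.389 CPM (SD, n = 3) in placebo CDH lungs, a log2 fold change of 8.10 with a standard error of 0.14 (edgeR adjusted p = 2.76e-08). ENSOCUG00000025982 stood at 218 ± 17.9 and 1.62 ± 0.353 CPM, a log2 fold change of 7.03 with a standard error of 0.14 (edgeR adjusted p = 4.85e-08). In control lungs they stood at 569 ± 17.8 and 198 ± 17.8 CPM (SD, n = 2), and their log2 differences between exposed and control lungs were 0.04 and 0.14, each with a standard error of 0.10 (edgeR adjusted p = 0.862 and 0.438). The largest falls under the same conditions ran the other way. ENSOCUG00000029101 fell from 901 ± 142 CPM in placebo to 1.92 ± 1.96 CPM in exposed CDH lungs, a log2 fold change of -8.77 with a standard error of 0.48, and ENSOCUG00000029112 fell from 1426 ± 252 to 3.24 ± 2.87 CPM, a log2 fold change of -8.71 with a standard error of 0.49 (edgeR adjusted p = 7.33e-05 for each). Both also had few counts in control lungs, with 3 counts of ENSOCUG00000029101 in each control library and 7 and 12 counts of ENSOCUG00000029112.

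These falls belonged to a block of neighbouring entries. Lines of the count table held 1 run of 37 consecutively numbered IDs, and the next longest such run held 3. Of its members, 16 were under 1 CPM in placebo CDH lungs. Another 15 were at least 10 times higher in the placebo CDH mean than in any exposed or control library, and together they took 10487 to 13356 CPM in the placebo CDH libraries, 28.1 to 81.4 CPM in the exposed libraries and 16.4 and 14.5 CPM in the controls. The other 6 members differed less, with placebo CDH means 1.40 to 6.34 times those of exposed lungs. The run held 2.33% of the counts in placebo CDH, 0.698% in exposed CDH and 0.637% in control lungs. It contributed 18 of the 156 lower calls, and without the run and the 2 largest rises, an alternative added after seeing the data, 37 higher and 127 lower IDs were called, all of them among the original 206.

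**Figure D2:**
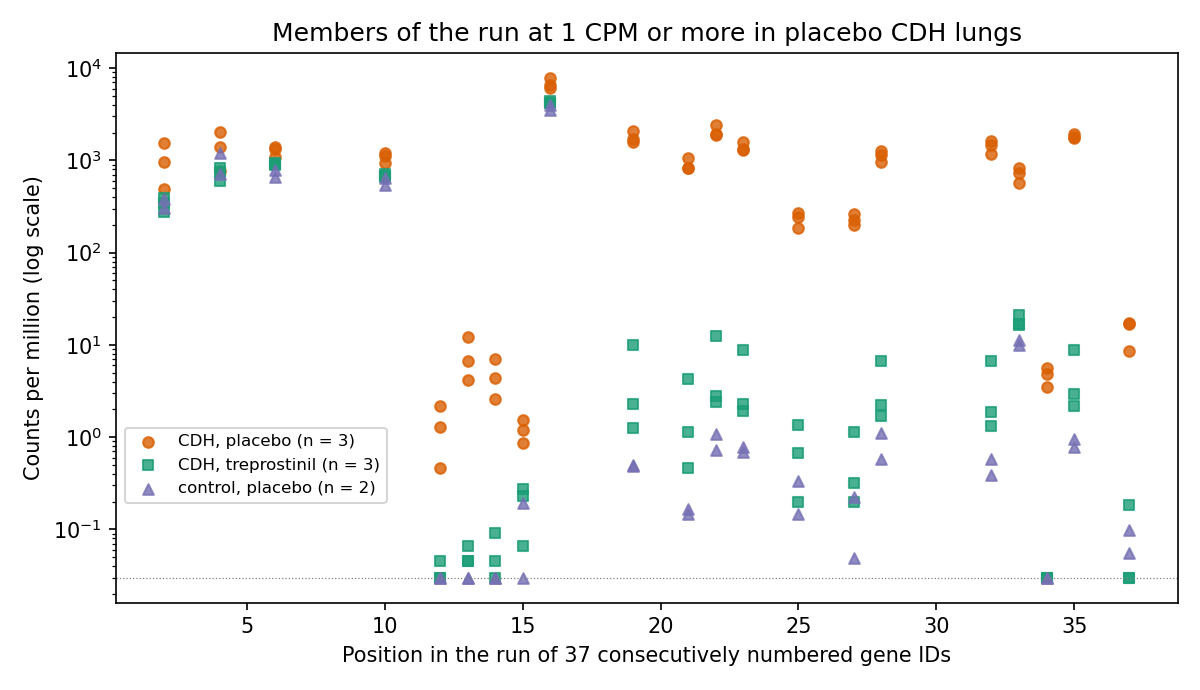
CPM (log scale) of the 21 members of the run that reached 1 CPM in placebo CDH lungs, against their position among the 37 IDs, 1 point per library, with libraries without a count drawn at 0.03 on the dotted line. From position 19 on, placebo CDH libraries (circles) lie far above exposed CDH (squares) and control libraries (triangles), whereas the abundant members up to position 16 are present in every library.

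Outside that run and the 2 on/off rises, the changes were smaller. The largest rise that met the naming conditions, apart from the 2 IDs above, was 15.98-fold, from 0.537 ± 0.285 CPM in placebo to 8.82 ± 2.36 CPM in exposed CDH lungs, with 4.55 ± 0.757 CPM in controls (edgeR adjusted p = 0.00212). The next was 11.4-fold, from 1.23 ± 0.388 to 13.7 ± 1.51 CPM, with 9.87 ± 1.22 CPM in controls. An ID that rose 4.23-fold, from 9.39 ± 3.09 to 39.6 ± 6.29 CPM, stood at 12.3 ± 1.10 CPM in controls. The largest fall outside the run under the same conditions was 11.1-fold, from 5.601 ± 1.85 to 0.473 ± 0.294 CPM, with 11.6 ± 0.196 CPM in controls (log2 fold change -3.48, standard error 0.42, edgeR adjusted p = 0.00885). Among more abundant genes, 1 ID fell 2.89-fold, from 93.5 ± 21.9 to 32.4 ± 6.19 CPM, with 79.9 ± 5.21 CPM in controls. These 5 IDs were chosen after their values were seen.

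The count of calls moved with the library left out. It was 91, 57 and 175 without placebo CDH replicates 1, 2 and 3. Without exposed CDH replicates 1, 2 and 3 it was 185, 60 and 43. It also fell without either control replicate, although controls enter this comparison only through the shared fit. Every one of the 206 IDs kept its direction in each alternative that tested it. Since their libraries did not overlap between the groups, this was largely fixed by the selection. Exposed libraries all carry title code 81 and placebo CDH libraries carry 61 or 56, so treatment and code cannot be told apart.

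The CDH comparison asked how placebo CDH lungs differed from control lungs. Here 122 IDs were higher and 209 lower in CDH lungs (edgeR, adjusted p under 0.05), which is 2.28% of the IDs. The median fold was 1.98 (quartiles 1.53 and 5.26) for higher and 1.64 (quartiles 1.41 and 2.29) for lower genes, and 60 higher and 64 lower IDs reached a log2 change of 1. The same run contributed 19 calls: ENSOCUG00000029112 was higher in CDH lungs by 11.46 on the log2 scale, with a standard error of 0.72 (edgeR adjusted p = 0.000139). ENSOCUG00000026762 and ENSOCUG00000025982 were lower by log2 fold changes of -8.07 and -6.89, each with a standard error of 0.14 (edgeR adjusted p = 3.40e-08 and 7.11e-08). Without the run and these 2 IDs, 98 higher and 195 lower IDs were called.

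Several of the largest changes against control were shared by both kinds of CDH lung. An ID with 885 to 1754 counts per placebo CDH library and 1472 to 2025 per exposed library had 3 and 0 counts in the controls. Another stood at 15.97 ± 3.30 CPM in placebo and 19.97 ± 5.03 CPM in exposed CDH lungs and at 0.344 ± 0.0607 CPM in controls (log2 fold change of placebo CDH against control 5.52, standard error 0.38, edgeR adjusted p = 0.000262). A more abundant ID stood at 113 ± 36.3, 107 ± 24.8 and 5.59 ± 1.24 CPM in placebo CDH, exposed CDH and control lungs, a 20.3-fold rise in placebo CDH. Among the falls, an ID with 160 and 198 counts in the controls had 0, 0 and 1 counts in the placebo CDH libraries and 3, 0 and 1 in the exposed ones. Another fell 29.2-fold, from 8.91 ± 1.54 CPM in controls to 0.289 ± 0.0643 CPM in placebo CDH, with 0.304 ± 0.0757 CPM in exposed CDH lungs.

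With 2 control libraries the CDH count was sensitive to each of several libraries. It was 57 and 50 without control replicates 1 and 2, where the remaining control was assumed to vary like the other groups, 182 and 90 without placebo CDH replicates 1 and 2, and 193 without exposed CDH replicate 3. Controls carry title code 83 only, so the hernia and the code cannot be told apart.

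Exposed CDH lungs were then set against control lungs, to show how far treated lungs remained from control. In this comparison 353 IDs were higher and 774 lower in exposed CDH lungs (edgeR, adjusted p under 0.05), 7.77% of the IDs. Changes were modest, with median folds of 1.58 for higher and 1.49 for lower genes, and 106 higher and 140 lower IDs reached a log2 change of 1. Only 1 call lay in the run. Of the CDH calls, 57 higher and 162 lower IDs were called in the same direction here, and 96 of the 156 IDs lower after treprostinil and 22 of the 50 higher ones were also called, in the same direction, against control. Independent lists of these lengths would share 2.97, 11.2, 8.32 and 1.22 IDs. These comparisons share libraries, so lists of the same lengths were also taken by smallest p from 20 simulated tables of unchanged groups. They shared 46 to 65 and 82 to 105 IDs for the higher and lower CDH lists, and 57 to 82 and 10 to 22 IDs for the lower and higher treprostinil lists. The observed 57 and 22 lay within these ranges. The observed 162 and 96 lay above them, where part of the excess may still come from the shared libraries. The simulated lists hold only chance differences, which the libraries shared here push in the same direction. These overlaps therefore do not decide whether real differences were shared. The count was 66 and 252 without control replicates 1 and 2, and 571 and 444 without exposed CDH replicates 2 and 3. Title codes 81 and 83 separate these groups, and whether exposed lungs differed from control in more genes than placebo CDH lungs did was not tested.

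The last comparison asked whether treprostinil moved genes against the direction in which they differed between placebo CDH and control lungs. Of the 206 and 331 calls, 48 were in common, and 47 of these went in opposite directions: 36 were higher in CDH and lower after treprostinil, and 11 were lower in CDH and higher after treprostinil. Independent lists would share 1.31 and 0.720 IDs. Lists of the same lengths, taken by smallest p from 20 simulated tables of unchanged groups that share the placebo CDH libraries, shared 12 to 27 and 13 to 24 IDs. Outside the run and the 2 opposite IDs, 18 and 9 IDs were shared, against 10 to 25 and 13 to 24 in simulated lists of those shorter lengths. With the run, the 36 lay above its simulated range and the 11 below. Outside the run and the 2 opposite IDs, the 18 lay within its range and the 9 below. The simulated lists hold only chance differences, which shared libraries push in opposite directions. These overlaps therefore do not decide whether real differences were opposed. Across all 14507 IDs the log2 fold changes had a Pearson correlation of -0.53 and a Spearman correlation of -0.20, across genes. Simulated unchanged groups gave a Pearson correlation of -0.47 ± 0.02 (SD, 20 simulations), because both effects contain the placebo CDH libraries. The covariance was -0.172, against -0.0391 ± 0.00217 in simulation, and -0.0793 outside the run and the 2 opposite IDs. The Pearson correlation outside them was -0.35. Real group differences widen the spread of both fold changes, so neither Pearson correlation is directly comparable with that of simulated unchanged groups. The Spearman correlation was not set beside a simulated value. Over all tested IDs, 56.1% had opposite signs in the CDH and treprostinil effects, against 65.3% in simulated unchanged groups. By sign, the opposition was thus weaker than shared libraries alone gave, although real differences alter this share too. Of the 331 CDH calls, 227 (68.6%) had the opposite sign after treprostinil, with 80.3% of the 122 higher and 61.7% of the 209 lower calls. Equally long lists from the simulated unchanged groups had the opposite sign in 84.3% to 91.8% of IDs, and in 80.3% to 91.8% and 84.7% to 92.8% for the higher and lower ones. The observed 68.6% of all CDH calls and 61.7% of the lower ones lay below these ranges. The 80.3% of the higher calls lay at the lower end of its range. These simulated lists also hold only chance differences, so the shares do not decide whether real differences were opposed. With different placebo CDH libraries in the CDH and the treprostinil effect, outside the run and the 2 opposite IDs, the covariance was -0.0236 and -0.0232 when the single library in the treprostinil effect was replicate 1 or 2, which is 12.5 and 10.9 SD below simulated unchanged groups. With replicate 3, of title code 56, in that place it was 0.00195, within 2 SD of the simulated value. IDs vary independently in the simulations, so their SD may be smaller than the spread between real libraries. Each division leaves 1 placebo CDH library on one side, so part of the excess in the full comparison may come from the shared libraries.

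**Figure D3:**
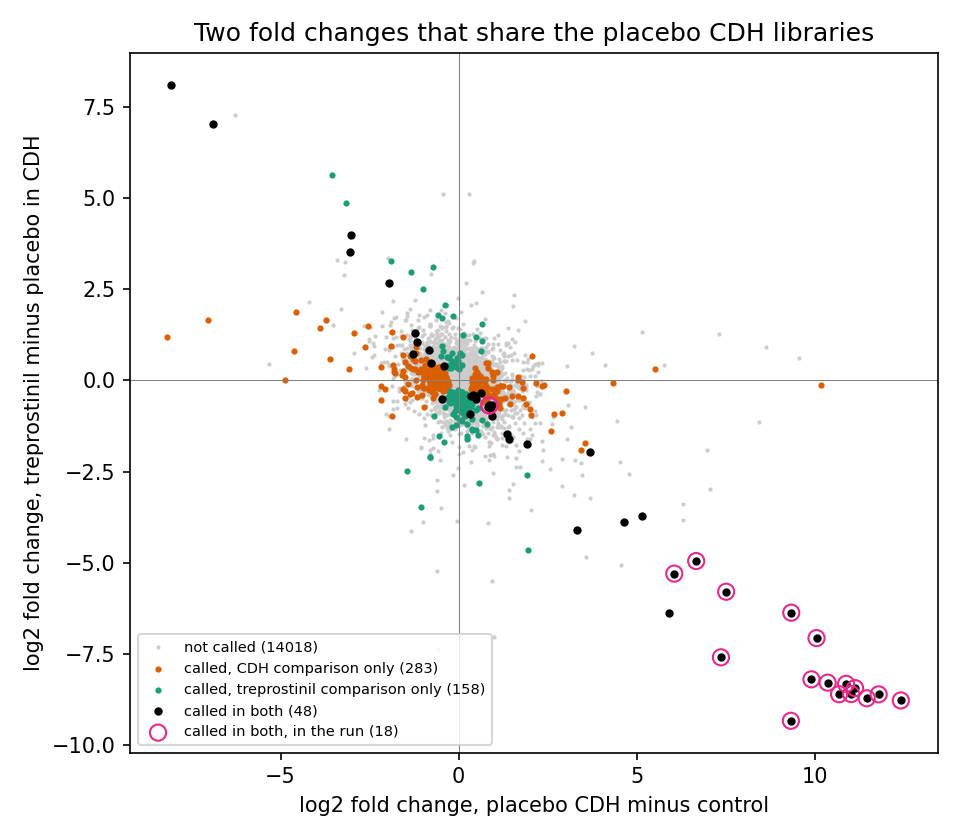
Log2 fold change of exposed against placebo CDH lungs (vertical) plotted against that of placebo CDH against control lungs (horizontal) for 14507 gene IDs, 1 point per ID, colored by the comparison in which it was called. Of the 48 IDs called in both, 47 changed in opposite directions, and the 18 that belong to the run (rings) include those at the lower right.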

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

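All alternatives below were chosen before the data were examined, except the fit without the run of 37 IDs and the 2 opposite IDs. Each called ID of the 3 comparisons kept its direction in every alternative that tested it. For none of them did the libraries of the groups compared overlap, so this was largely fixed by the selection. RLE scaling moved the median log2 change of all IDs by under 0.1. RLE scaling, both other filters on low counts and limma voom left each count of calls within 1.5 times of the reported one. The cause was not tested for the following shifts, except where fewer samples or IDs entered. DESeq2 called 642 IDs in the treprostinil comparison, 903 in the CDH comparison and 1775 for exposed CDH against control, and these included all 206, all 331 and 1112 of the 1127 IDs called by edgeR. Fitting only the groups compared gave 90 treprostinil calls and 202 CDH calls, from fewer samples. Leaving out 1 library at a time gave 43 to 185 treprostinil calls, 50 to 443 CDH calls and 66 to 1282 calls for exposed CDH against control. With the last number of the title's code as a replicate block, 24, 94 and 215 IDs were called. That number does not pair the libraries: the deviations of same-numbered libraries from their group means correlated at -0.07 to 0.07 over 8 pairs. The covariance of the CDH and treprostinil effects (-0.172) was -0.141 with 1 CPM required in 3 libraries, which tests fewer IDs, -0.0794 without the run and the 2 opposite IDs, and -0.236 to -0.165 when 1 library was left out. Of 180 refits of the 4 named IDs, 178 stayed on the same side of the threshold, and DESeq2 alone called ENSOCUG00000029101 and ENSOCUG00000029112 higher in exposed CDH than in control lungs. The planned tests of gene lists were not run, because no ID could be paired with a gene name. At this depth and sample size, 71.3% of simulated IDs changed by a fold of 2 were called in the treprostinil comparison, so smaller changes are under-counted.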

Other observations

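Apart from the count of splits and the covariance with different placebo CDH libraries over all 3 divisions, whose tests were set down before their own results were known, the tests here were chosen only after the result was seen. Several also replaced or divided an earlier test that was undecided or covered too little, and both outcomes are given. Those are the shift of fold changes beside the share of calls kept, the covariance by title code beside that over 3 divisions, the gain of IDs at any fold beside that of IDs with a 10-fold split, and the share of opposite signs beside the covariance for code 56.

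Some IDs were on in 1 library of a group and off in another. With 5 CPM or more in the highest library and a 32-fold range, there were 13 such IDs among the 3 placebo CDH libraries, 11 among the 3 exposed ones and 8 between the 2 controls. Among IDs averaging 1000 CPM or more, 5 differed at least 4-fold between the controls. Together they took 5.54% of the counts in control replicate 2, 1.05% in control replicate 1 and 0.921% to 2.02% in the CDH libraries. To see whether title codes differ within a group, each CDH library was set against the others of its group: the code 56 library gave 5 calls by edgeR and the highest other library, exposed CDH replicate 1, gave 12, so this did not decide whether the codes differ.

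For the 206 treprostinil calls, 1 of the 10 splits of the 6 CDH libraries into 3 and 3, the real one, gave as many calls, and the highest of the other splits gave 3. With 10 splits a share under 0.05 cannot be reached.

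The 15 strongly split members of the run of 37 IDs stood in exposed lungs at 0.240% to 0.695% of their placebo CDH mean and in controls at 0.124% and 0.140%, while other members stayed abundant in every library. Reads counted instead at IDs with few counts in placebo CDH lungs are argued against as the whole account. IDs at least 10 times higher in each exposed and control library gained 6.74% of what the run lost (5.40% to 8.47% over pairs of libraries). Without that fold minimum 542 IDs gained 60.9%. These were picked for being higher and include real differences, so their gain decides nothing and a move to abundant IDs stays open. As to distortion of other genes, 88.2% of the 186 other treprostinil calls were kept without the run and the 2 opposite IDs, which left the question undecided, but no fold change among them moved by more than 0.00124 on the log2 scale, against a median standard error of 0.0916. Treatment acting on the run and a difference between title codes cannot be told apart, because 0 title codes hold libraries of 2 groups. Reads lost between near-identical sequences, or sequence variants that differ between animals, remain candidate explanations that were not tested, since they need the reads.

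Outside the run, the opposition between the CDH and the treprostinil effect may be in part a property of the code 61 libraries, a hypothesis that rests on 1 library of code 56. Of 61 IDs called in opposite directions by the fit without that library, it lay beyond every exposed and control library, on the side of code 61, in all 18 of the run and in 20 of the 41 outside the run and the 2 opposite IDs. The latter share, 48.8%, lay within the 33.3% to 58.3% of equally made lists from simulated unchanged groups and decides nothing. With different placebo libraries in each effect and the run left out, the 3 divisions disagreed and left the test undecided. The covariance was -0.0236 and -0.0232 where code 61 stood on both sides, 12.5 and 10.9 SD below simulated unchanged groups. This argues against shared libraries as the whole account there only as far as IDs vary independently, as simulated. With the code 56 library alone in the treprostinil effect the covariance was 0.00195, within 2 SD of the simulated value. Of 422 IDs called in the CDH comparison without code 56, 40.8% went the opposite way against the code 56 library. Against the code 61 libraries, which had also defined the calls, 79.1% did. A feature common to both placebo codes, the hernia included, and a difference between codes cannot be told apart with 1 library of code 56.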
